A study of Mus musculus with 9 samples.

How the data were processed

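The deposited values are log2 signals per transcript cluster of a whole-transcript array, normalized by the authors with RMA (robust multi-array average) in Partek 6.6, per the submitters' processing notes. Total RNA was extracted with TRIzol and labelled with the Affymetrix WT PLUS kit, per the labels' protocols. The model of the array, the genome build behind its clusters and any filter, background or batch step were not given in the sources used here, so no genomic positions are reported. The range of the values (array medians of 5.7 to 5.8 and maxima of 13.64 to 13.73) is that of log2 RMA signals, and they were used without further scaling. The labels give no batch, slide or sex of the animals, and replicate numbers are not shared between groups.

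The value table holds 41345 rows, of which 23521 carry 1 gene symbol in the annotation used, 1814 carry several and 16010 carry none. Genes were tested from rows with 1 symbol, and where a gene had more than 1 such row, the row with the highest mean signal over the 9 arrays was taken, which left 1341 rows unused and 22180 genes. Of the genes' identifiers, 21994 were found in the gene table of the reference. Spp1, Slc51b and some members of the lists have no row with a single symbol and were not analysed here. No gene was left out for low signal.

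Differences between groups were estimated with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 9 arrays in the fit and a moderated variance per gene (6 residual and 3.77 prior degrees of freedom). A gene is said to have risen, fallen or been called when its Benjamini-Hochberg adjusted p over the 22180 genes was under 0.05 (two-sided). Every adjusted p of a gene is from this fit, every change is a difference of mean log2 signals with its standard error (SE), and SD is the spread over the 3 arrays of a group. The 3 comparisons were CBDL minus sham, norUDCA-fed CBDL minus CBDL and norUDCA-fed CBDL minus sham.

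The comparisons, 17 gene lists (tubular injury, extracellular matrix and fibrosis, chemokines with adhesion and NF-kB targets, complement and acute phase, interferon response, bile acid transport and metabolism, NRF2 and xenobiotic metabolism, cholesterol biosynthesis, fatty acid oxidation and PPARA targets, mitochondrial respiratory chain, cell cycle, unfolded protein and integrated stress response, hypoxia and glycolysis, renin-angiotensin and vascular tone, immediate early genes, circadian clock, male-biased kidney genes) and 12 marker lists (proximal tubule, thick ascending limb and distal convoluted tubule, collecting duct, podocyte, endothelium, macrophage and myeloid, lymphocyte, neutrophil, erythroid and blood, urothelium, adrenal, adipose) were fixed before the data were examined. Lists with at least 5 measured members were tested, which left out the erythroid list, and the adjustment of list tests runs over the 28 lists of a comparison. camera with a preset correlation of 0.01 compares the genes of a list with all other genes, and its call is the one reported. camera with a correlation estimated per list and fry, which asks only whether a list's own genes move, on balance, in 1 direction, were run beside it. Counts adjusted over the list alone use the Benjamini-Hochberg method on the members of the list only.

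The named genes were chosen by a rule fixed at the same time. Per comparison it takes the 10 genes with the largest increase and the 10 with the largest decrease among called genes whose 3 and 3 values do not overlap, per list up to 4 members with the lowest p, and the 10 genes with the lowest p in norUDCA-fed CBDL against CBDL. It always takes Havcr1, Lcn2, Vcam1, Col1a1, Aqp2, Slc10a2, Slc51a, Abcc2 and Abcc4. Genes printed for a comparison in which the rule does not take them (Lrp2 in CBDL against sham and Mki67 in norUDCA-fed CBDL against sham among them), those it takes in none (Mrc1, Slc13a1 and Cry2) and most genes named in the closing parts were chosen after their values were seen.

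The change of ligation-called genes in norUDCA-fed CBDL was counted from the calls of both fits and measured again with 1 CBDL array held out, with genes and their directions taken from the other arrays. Overlaps were set against lists drawn independently and against 100 simulations with no effect that kept the shared arrays. A self-test planted changes in 100 genes at 1.5-fold and in 100 at 2-fold in data with the spread of these arrays. The fit recovered 33%, 43% and 29% of the first and 87%, 93% and 84% of the second in the 3 comparisons, and 7.7%, 2.2% and 6.6% of the calls were genes with no planted change. camera called 0 of 29 random lists by the same threshold. Genes were simulated as independent, so this does not test camera on lists whose genes vary together. The held-out measure gave 49.6% for a planted return of 50%.

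The alternatives were an intensity trend in the prior variance, estimated array weights, variances that are not moderated, only the 6 arrays compared in the fit, leaving out the dimmest 33.3% of genes (mean log2 signal under 5.2, 14786 genes kept), the mean of a gene's rows, all rows tested, arrays centred on their median, repeated quantile normalization, a 1.5-fold minimum beside the adjusted or the unadjusted p, and each array left out in turn. Centring used the median over the genes tested. Leaving out sham_159 and CBDL_165 together was added after the data were seen. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.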

Results

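The data were 9 whole-transcript array measurements of mouse kidney RNA in 3 groups of 3 samples. The first group had a sham operation 3 weeks earlier. The second had its common bile duct ligated for 3 weeks, which blocks the flow of bile from the liver, and is called CBDL. The third was fed norursodeoxycholic acid (norUDCA), a bile acid with a shortened side chain, for 5 days before the same 3 weeks of ligation and is called norUDCA-fed CBDL. The labels do not say whether the feeding went on after the operation. Arrays are named by their group and the number in their label, sham_158, sham_159 and sham_160, CBDL_164, CBDL_165 and CBDL_170, and norUDCA_CBDL_172, norUDCA_CBDL_175 and norUDCA_CBDL_179. A sham group fed norUDCA was not among the samples. The median log2 signal over all 41345 rows of the value table lay between 5.7 and 5.8 on the 9 arrays and the highest signal between 13.64 and 13.73. The number of arrays limits the precision, and the median standard error of a difference between groups was 0.14. The p-values measure only the spread between these samples, since the labels do not say how the replicates of a group were obtained. An exact permutation test of 3 arrays against 3 cannot go below a two-sided p of 0.1, so calls rest on limma, which shares information on spread across genes.

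Xist, a transcript of the inactive X chromosome, lay between 3.66 and 4.39 on the 9 arrays. The Y-linked transcripts Kdm5d, Eif2s3y and Uty were high on 8 arrays and lower on norUDCA_CBDL_172, at 6.46, 7.64 and 7.66 against at least 7.89, 8.49 and 9.15 elsewhere. Correlations across genes between arrays of the same group were between 0.986 and 0.995, and genes are not independent replicates. The first principal component held 58.3% of the variance, with sham arrays between -42.2 and -34.1, norUDCA-fed CBDL arrays between -6.6 and 0.5 and CBDL arrays between 26.1 and 57. The second held 13%, and sham_159 at -34.5 and CBDL_165 at -22.9 stood apart from the other arrays, which lay between 3.4 and 12.

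The comparison of CBDL with sham addresses what ligation of the bile duct does to kidney transcripts. After ligation 19 of 22 tubular injury genes, 27 of 27 extracellular matrix genes and 19 of 20 macrophage markers rose, while 21 of 22 proximal tubule markers and 15 of 17 genes of the mitochondrial respiratory chain fell. Each of these 5 lists passed camera, and with an estimated correlation none did (adjusted p between 0.0502 and 0.274). Lcn2, which encodes an iron-carrier-binding protein released by injured tubules, went from 7.43 ± 0.38 (SD, n = 3) in sham to 12.09 ± 0.31 (SD, n = 3) in CBDL. Havcr1, a marker of injured proximal tubule, went from 5.24 ± 0.87 to 9.12 ± 0.71 (SD, n = 3 each), and Col1a1, a chain of type I collagen, from 7.72 ± 0.35 to 10.78 ± 0.23 (SD, n = 3 each). Of 22180 genes tested, 4844 were called (21.8%), of which 2293 rose and 2551 fell, and 1355 differed at least 2-fold (686 higher and 669 lower). An unadjusted p under 0.05 was reached by 7379 genes, and the CBDL and sham arrays did not overlap for 7889 genes (35.6%, where chance gives 10%).

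**Figure D1:**
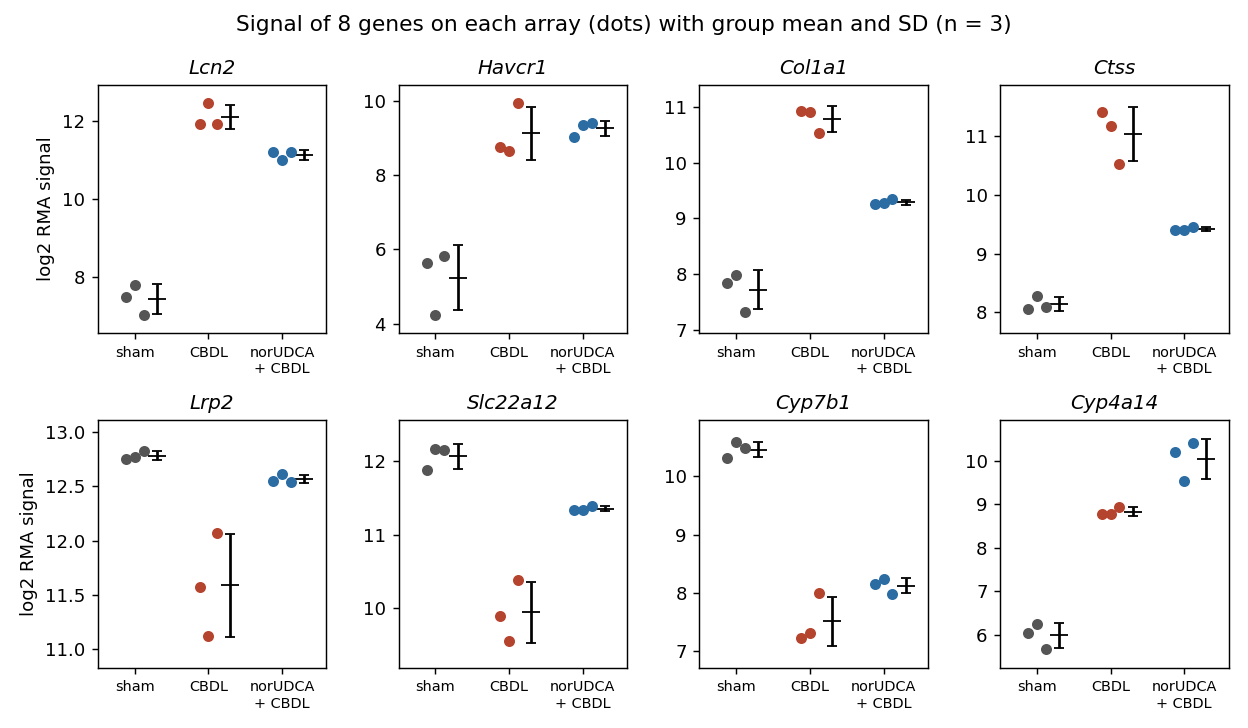
Log2 RMA signal (vertical axis) of 8 genes in sham, CBDL and norUDCA-fed CBDL kidneys, with 1 dot per array and the mean and SD of each group (n = 3) beside the dots. Lcn2 averaged 7.43 in sham, 12.09 in CBDL and 11.12 in norUDCA-fed CBDL, and Cyp4a14 averaged 5.99, 8.83 and 10.05.

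The genes with the largest increases were Serpina3n, an inhibitor of serine proteases, at 5.81 (SE 0.34, adjusted p = 1.85e-05), then Lcn2 at 4.65 (SE 0.20, adjusted p = 6.27e-06), Mmp7, a matrix metalloproteinase, at 4.18 (SE 0.42, adjusted p = 0.00013), and Timp1, an inhibitor of such enzymes, at 4.06 (SE 0.23, adjusted p = 1.82e-05). The next were Chil3 at 3.99, Havcr1 at 3.89 (SE 0.43, adjusted p = 0.000211), Tnc, a matrix glycoprotein, at 3.84, Npy6r at 3.68, Ms4a4a at 3.59 and Krt20, a keratin, at 3.57. The largest decrease was that of Dnase1, a secreted deoxyribonuclease, which went from 12.18 ± 0.17 to 6.63 ± 0.74 (SD, n = 3 each), a change of -5.55 (SE 0.32, adjusted p = 1.84e-05). It was followed by Cyp2d12 at -5.17, the predicted gene Gm6300 at -4.95, Pzp at -4.74, the organic anion transporter gene Slc22a7 at -4.40 (SE 0.44, adjusted p = 0.000123), the amino acid transporter gene Slc7a13 at -4.37, Akr1c14 at -4.36, Slc22a22 at -4.24, Inmt at -4.23 and the brush border protease gene Mep1b at -3.99. The sham means of Chil3, Npy6r, Ms4a4a, Krt20, Timp1 and Mmp7 and the CBDL means of Cyp2d12 and Gm6300 were under 5.2. Below that level the dimmest 33.3% of genes lie and signal above background is not shown, so the size and ranking of these differences are open. Cyp2d12, Slc22a7, Slc22a22, Akr1c14 and Serpina3n belong to families of closely related genes, and whether their probes also read a relative was not tested here.

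Of the 22 measured genes of tubular injury, 19 rose, 0 fell and 3 did not pass (21 rose and 0 fell adjusted over the list alone). Beside Lcn2, Havcr1 and Krt20, Cd44 changed by 2.66 (SE 0.13, adjusted p = 9.39e-06) and Vcam1 by 2.41 (SE 0.16, adjusted p = 2.52e-05). The tubular injury list had a median of 2.10 (camera adjusted p = 8.48e-23, adjusted p = 0.0502 with an estimated correlation). Each of the 27 measured genes of extracellular matrix and fibrosis rose, over all genes and when adjusted over the list alone, with Col1a1 at 3.06 (SE 0.17, adjusted p = 1.84e-05), Lox, which cross-links collagen, at 3.16 and Mmp14 at 2.96. The matrix list had a median of 1.58 (camera adjusted p = 5.03e-29, adjusted p = 0.0519 with an estimated correlation). Of 20 macrophage and myeloid markers, 19 rose, 0 fell and 1 did not pass (20 rose and 0 fell adjusted over the list alone). Ctss changed by 2.88 (SE 0.19, adjusted p = 2.82e-05), Laptm5 by 1.57 and C1qc by 2.18. The macrophage list had a median of 1.84 (camera adjusted p = 1.11e-20, adjusted p = 0.0519 with an estimated correlation). Of 20 genes of chemokines, adhesion and NF-kB targets, 15 rose, 0 fell and 5 did not pass (18 rose and 0 fell adjusted over the list alone). Cxcl1 changed by 2.08 (SE 0.19, adjusted p = 8.41e-05), Csf1 by 1.38 and Tnf by 0.96. The chemokine and NF-kB list had a median of 0.82 (camera adjusted p = 9.89e-13, adjusted p = 0.0222 with an estimated correlation). Of 13 complement and acute phase genes, 6 rose, 0 fell and 7 did not pass (6 rose and 1 fell adjusted over the list alone). Cfi changed by 2.87, Cp by 2.53 and C4b by 2.02. The complement and acute phase list had a median of 1.35 (camera adjusted p = 7.5e-06, adjusted p = 0.0519 with an estimated correlation). Of 26 cell cycle genes, 19 rose, 0 fell and 7 did not pass (22 rose and 0 fell adjusted over the list alone). Mki67 changed by 1.96 (SE 0.17, adjusted p = 6.68e-05), Ccnb2 by 1.12 and Mcm5 by 0.89. The cell cycle list had a median of 0.61 (camera adjusted p = 3.66e-12, adjusted p = 0.0519 with an estimated correlation). Of 13 immediate early genes, 10 rose, 0 fell and 3 did not pass (11 rose and 0 fell adjusted over the list alone). Atf3 changed by 1.22 (SE 0.12, adjusted p = 0.000116), Junb by 1.42 and Btg2 by 1.35. The immediate early list had a median of 1.10 (camera adjusted p = 9.48e-09, adjusted p = 0.0786 with an estimated correlation).

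Of 22 proximal tubule markers, 0 rose, 21 fell and 1 did not pass (1 rose and 21 fell adjusted over the list alone). The proximal tubule list had a median of -1.68 (camera adjusted p = 7.39e-12, adjusted p = 0.274 with an estimated correlation). Slc22a12, the urate exchanger, fell by 2.11 (SE 0.18, adjusted p = 6.68e-05), Slc17a3 changed by -2.23, Slc6a19 by -1.54 and Lrp2, the endocytic receptor megalin, by -1.20. Of 17 genes of the mitochondrial respiratory chain, 0 rose, 15 fell and 2 did not pass (0 rose and 15 fell adjusted over the list alone). Uqcrfs1 changed by -1.08 (SE 0.13, adjusted p = 0.000333), Cyc1 by -0.90 and Sdhb by -0.79. The respiratory chain list had a median of -0.65 (camera adjusted p = 8.55e-10, adjusted p = 0.158 with an estimated correlation). Of 21 genes of fatty acid oxidation and PPARA targets, 1 rose, 10 fell and 10 did not pass (1 rose and 13 fell adjusted over the list alone). The fatty acid oxidation list had a median of -0.41 (camera adjusted p = 0.00396, adjusted p = 0.589 with an estimated correlation). The acyl-CoA enzymes Acadm at -0.90, Acaa1b at -1.19 and Ehhadh at -1.46 fell, and the member that rose was Cyp4a14, a fatty acid hydroxylase, at 2.84 (SE 0.22, adjusted p = 4.27e-05). Of 11 male-biased kidney genes, 0 rose, 10 fell and 1 did not pass (0 rose and 10 fell adjusted over the list alone). Cyp4a12a changed by -3.50 (SE 0.31, adjusted p = 7.07e-05), Ugt2b38 by -2.91 and Cyp2j13 by -2.12. The male-biased list had a median of -2.91 (camera adjusted p = 8.58e-09, adjusted p = 0.158 with an estimated correlation).

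Of 22 genes of bile acid transport and metabolism, 5 rose, 8 fell and 9 did not pass (5 rose and 9 fell adjusted over the list alone). The bile acid list did not pass camera (median -0.34, camera adjusted p = 0.269) but passed fry (adjusted p = 0.0156), which asks only whether a list's own genes move, on balance, in 1 direction. Cyp7b1, an oxysterol hydroxylase, changed by -2.95 (SE 0.19, adjusted p = 2.36e-05) and the transporter gene Slco4c1 by -2.10, while the efflux transporter genes Abcc3 at 2.17 (SE 0.24, adjusted p = 0.000209) and Abcc4 at 0.92 rose and Abcc2 at -0.71 fell. Slc10a2, the apical bile acid uptake transporter, changed by -1.21 (SE 0.30, adjusted p = 0.0157), a call that ended without sham_159 (adjusted p = 0.0519), and Slc51a differed by -0.79 (adjusted p = 0.281). Of 16 cholesterol biosynthesis genes, 1 rose, 5 fell and 10 did not pass (2 rose and 6 fell adjusted over the list alone). The cholesterol biosynthesis list had a median of -0.18 (camera adjusted p = 0.165). Cyp51 changed by -2.03 (SE 0.30, adjusted p = 0.000972) and Hmgcs1 by -0.89. Of 18 genes of NRF2 and xenobiotic metabolism, 3 rose, 3 fell and 12 did not pass (4 rose and 3 fell adjusted over the list alone). The NRF2 list had a median of -0.11 (camera adjusted p = 0.827). Gsta4 changed by 0.95 and the carboxylesterase gene Ces1f by -3.54. Of 14 hypoxia and glycolysis genes, 4 rose, 3 fell and 7 did not pass (4 rose and 3 fell adjusted over the list alone), and the median of -0.18 differed in sign from the mean of 0.04 (camera adjusted p = 0.954). Hk2, a hexokinase, rose by 2.11 (SE 0.11, adjusted p = 1.75e-05), Car9 changed by -0.98 and Vegfa by -0.43. Of 11 genes of the renin-angiotensin system and vascular tone, 3 rose, 2 fell and 6 did not pass (3 rose and 2 fell adjusted over the list alone). Edn1, the endothelin precursor, changed by 2.69, Ptgs2 by 1.72 and Ace by -2.06 (SE 0.19, adjusted p = 8.41e-05) (list median -0.17, mean 0.14, camera adjusted p = 0.779). Of 14 circadian clock genes, 4 rose, 3 fell and 7 did not pass (4 rose and 6 fell adjusted over the list alone). Per1 changed by 1.69 (SE 0.21, adjusted p = 0.000376), Hlf by -1.19 and Nr1d1 by -0.99. The circadian list had a median of 0.11 (camera adjusted p = 0.798). Fdft1, the cholesterol biosynthesis gene that rose, lost its call without sham_160 (adjusted p = 0.0971), CBDL_164 (0.0635), CBDL_165 (0.0621) or CBDL_170 (0.0857). Without CBDL_164 or CBDL_165, 2 cholesterol biosynthesis genes fell, and 1 NRF2 gene rose without sham_159, sham_160 or CBDL_165.

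Of 17 interferon response genes, 3 rose, 1 fell and 13 did not pass (3 rose and 1 fell adjusted over the list alone). The interferon list had a median of 0.27 (camera adjusted p = 0.0227, adjusted p = 0.606 with an estimated correlation). Gbp3 at 1.58, Psmb8 at 0.90 and Oasl2 at 0.73 rose and Rsad2 at -0.98 fell, and the list's call ended without sham_160 (adjusted p = 0.106), CBDL_164 (0.112) or CBDL_170 (0.0605). Oasl2 lost its call without any 1 of 7 arrays (adjusted p up to 0.149), as did Xbp1 (up to 0.112), which with Asns makes the stress response genes that rose. Of 15 genes of the unfolded protein and integrated stress response, 2 rose, 0 fell and 13 did not pass (1 rose and 0 fell adjusted over the list alone). Asns changed by 0.76, and the stress response list had a median of 0 to 2 decimals (camera adjusted p = 0.732). Of 14 markers of the thick ascending limb and distal convoluted tubule, 2 rose, 6 fell and 6 did not pass (2 rose and 7 fell adjusted over the list alone). Klhl3 changed by -1.10, Pvalb by -1.20 and the calcium channel gene Trpv5 by 1.57 (SE 0.20, adjusted p = 0.000403). The thick ascending limb list had a median of -0.21 (camera adjusted p = 0.0964). It did not pass camera, passed fry (adjusted p = 0.0151) and passed camera without CBDL_164 (adjusted p = 0.0473). Of 16 collecting duct markers, 2 rose, 4 fell and 10 did not pass (2 rose and 5 fell adjusted over the list alone). The collecting duct list had a median of -0.30 (camera adjusted p = 0.41). The water channel gene Aqp3 changed by -1.39 (SE 0.27, adjusted p = 0.00525) and Scnn1a by 0.55. Aqp2 was 9.55 ± 0.49 in sham and 9.05 ± 0.72 in CBDL (SD, n = 3 each, adjusted p = 0.347). Without sham_158 or sham_159, 1 collecting duct marker fell, and 1 podocyte marker fell without any 1 of 5 arrays. Of 8 podocyte markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone). Plce1 changed by 0.82 and Clic5 by -0.52. The podocyte list had a median of 0.13 (camera adjusted p = 0.572). Of 12 endothelial markers, 0 rose and 1 fell (4 and 3 adjusted over the list alone). Kdr changed by -0.90 (SE 0.13, adjusted p = 0.000872) (list median 0.01, mean -0.05, camera adjusted p = 0.785).

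Among markers of other cell types that a kidney sample can hold, 3 of 9 adipose markers rose over all genes and 3 when adjusted over the list alone. The adipose list had a median of 0.88 (camera adjusted p = 0.00396, adjusted p = 0.522 with an estimated correlation). Adipoq changed by 2.10 (SE 0.27, adjusted p = 0.000495), Cidec by 3.13 and Retn by 2.25. Retn lost its call without sham_159, sham_160, CBDL_164, CBDL_170 or norUDCA_CBDL_175, with a highest adjusted p of 0.122. Adipoq was 5.51 ± 0.46 in sham, 7.61 ± 0.09 in CBDL and 6.13 ± 0.52 in norUDCA-fed CBDL (SD, n = 3 each), the same order of groups as in the medians of the injury, matrix and macrophage lists. Of 13 neutrophil markers, 4 rose and 0 fell (4 and 0 adjusted over the list alone). Csf3r changed by 0.89, and it alone rose without sham_160 or CBDL_165, where Cxcr2 (adjusted p = 0.076 and 0.11), Retnlg (0.0672 and 0.0807) and Mmp9 (0.0583 and 0.0511) lost their call. The neutrophil list had a median of 0.14 (camera adjusted p = 0.0918, and 0.0233 without CBDL_170). Of 16 lymphocyte markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone). The member called was Cd79a, at -0.72 (SE 0.13, adjusted p = 0.00291). The lymphocyte list had a median of -0.06 (camera adjusted p = 0.742). Of 6 urothelial markers none was called by limma and 2 had an unadjusted p under 0.05. The urothelial list had a median of 0.75 (camera adjusted p = 0.0964, passing at 0.00965 without sham_158 and at 0.00952 without CBDL_165). Of 10 adrenal markers limma called 0 and 0 had an unadjusted p under 0.05. The adrenal list had a median of 0.01 (camera adjusted p = 0.798). Of the erythroid list Slc4a1 was tested, at -1.30 (adjusted p = 0.0621). Whether it tracks blood was not. Across the 28 lists tested, camera passed 13, of which 9 rose and 4 fell, the list of chemokines, adhesion and NF-kB targets kept its call with an estimated correlation, and fry passed 13.

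Over the genes tested, the array medians of CBDL stood 0.105 above those of sham. With each array centred on that median the called genes became 1945 higher and 4547 lower, so that 30% were higher against 47.3% in the values as deposited. The share was 53.8% without sham_159 and 50.7% with repeated quantile normalization, so which direction prevails is open. Leaving out 1 array at a time gave between 3794 and 4604 called genes, and 11 of the 113 named genes called here lost their call without at least 1 array, with adjusted p values up to 0.149 for Oasl2.

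The comparison of norUDCA-fed CBDL with CBDL addresses what the feeding changes in the kidney of ligated mice. In the norUDCA-fed group 21 of 27 matrix, 15 of 22 tubular injury and 16 of 20 macrophage genes fell, and 16 of 22 proximal tubule, 6 of 16 cholesterol biosynthesis and 8 of 17 respiratory chain genes rose. These 6 lists passed camera, and with an estimated correlation none did (adjusted p between 0.101 and 0.139). With 1 array left out, the counts were as low as 14, 5, 4, 1, 1 and 0 in the same order. Col1a1 went from 10.78 ± 0.23 in CBDL to 9.29 ± 0.05 in norUDCA-fed CBDL (SD, n = 3 each), Ctss, a lysosomal protease of macrophages, from 11.03 ± 0.46 to 9.42 ± 0.03 (SD, n = 3 each) and Slc22a12 from 9.94 ± 0.42 to 11.35 ± 0.04 (SD, n = 3 each). Havcr1 was 9.12 ± 0.71 in CBDL and 9.27 ± 0.20 in norUDCA-fed CBDL (SD, n = 3 each) and did not pass the test, at 0.14 (SE 0.43, adjusted p = 0.921). Of 22180 genes, 1509 were called (6.8%), of which 800 rose and 709 fell, and 399 differed at least 2-fold (239 higher and 160 lower). The share of called genes that were higher, 53%, was 41.3% without CBDL_164, 42.4% without norUDCA_CBDL_179, 44.3% with only the 6 arrays compared in the fit and 40% with unmoderated variances, so which direction prevails is open. An unadjusted p under 0.05 was reached by 4275 genes, and the arrays of the groups did not overlap for 5368 genes (24.2%, where chance gives 10%).

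The 10 genes with the lowest p were Hk2 at -1.40 (SE 0.11, adjusted p = 0.00655), Sulf1 at -1.41 (SE 0.12, adjusted p = 0.00655), Spatc1l at 1.20, the collagen gene Col15a1 at -1.20, Rgs16 at -1.98, the metalloproteinase gene Adamts1 at -1.08, the AP-1 gene Fosl2 at -0.94, the matrix gene Fbln2 at -1.78, the inflammasome gene Nlrp6 at 1.63 and Etnppl at 2.46, each with an adjusted p of 0.00655. The largest increases were those of Cyp2d12 at 3.73 (SE 0.75, adjusted p = 0.0194), Slc22a22 at 2.81, Hpd, an enzyme of tyrosine breakdown, at 2.58, Serpina1d at 2.50, Etnppl, Slc22a19 at 2.45, the carboxylesterase Ces1e at 2.29 (SE 0.29, adjusted p = 0.00658), Dnase1 at 2.26 (SE 0.32, adjusted p = 0.00815), Bhmt2 at 2.24 and Aspdh at 2.16. The largest decreases were those of Mmp7 at -2.79 (SE 0.42, adjusted p = 0.00883), Col12a1 at -2.45, Hp, the haptoglobin gene, at -2.18 (SE 0.34, adjusted p = 0.00931), Npy6r at -2.12, Nkd2 at -2.08, Tnc at -2.06, Serpina3n at -2.04, the gelatinase gene Mmp2 at -1.99 (SE 0.29, adjusted p = 0.00815), Rgs16 and Mfap5 at -1.97. Slc22a19 (adjusted p up to 0.159), Serpina1d (0.15), Slc22a22 (0.115), Hpd (0.0766), Cyp2d12 (0.0737), Tnc (0.0654), Mfap5 (0.0603), Serpina3n (0.0581), Col12a1 (0.0516), Bhmt2 (0.0512) and Npy6r (0.05) lost their call without at least 1 array. For Slc22a19 and Serpina1d any 1 of 8 arrays sufficed. Cyp2d12 was 5.23, 2.68 and 6.27 on CBDL_164, CBDL_165 and CBDL_170. Its CBDL mean was under 5.2, so the size of its difference is open.

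Of 27 matrix and fibrosis genes, 0 rose, 21 fell and 6 did not pass (0 rose and 26 fell adjusted over the list alone). Col1a1 changed by -1.49 (SE 0.17, adjusted p = 0.00655), Mmp14 by -1.52 and Thbs1 by -1.51. The matrix list had a median of -0.88 (camera adjusted p = 5.23e-27, adjusted p = 0.101 with an estimated correlation). Of 22 tubular injury genes, 0 rose, 15 fell and 7 did not pass (0 rose and 17 fell adjusted over the list alone). Cd44 changed by -1.17 (SE 0.13, adjusted p = 0.00655), Sox9 by -1.52 and Plaur by -0.98. The tubular injury list had a median of -0.82 (camera adjusted p = 8.2e-13, adjusted p = 0.101 with an estimated correlation). Lcn2 at -0.97 (SE 0.20, adjusted p = 0.0232) and Vcam1 at -0.78 (SE 0.16, adjusted p = 0.0192) also fell, calls that ended without CBDL_164 or any 1 of the norUDCA-fed arrays, and for Lcn2 without CBDL_165 too, with adjusted p values up to 0.0974 and 0.0748. Of 20 macrophage and myeloid markers, 0 rose, 16 fell and 4 did not pass (0 rose and 19 fell adjusted over the list alone). Ctss changed by -1.61 (SE 0.19, adjusted p = 0.00655), C1qa by -1.21 and Ccr2 by -0.76. The macrophage list had a median of -0.93 (camera adjusted p = 6.54e-19, adjusted p = 0.101 with an estimated correlation). Of 20 genes of chemokines, adhesion and NF-kB targets, 0 rose, 8 fell and 12 did not pass (0 rose and 13 fell adjusted over the list alone). Csf1 changed by -0.94 (SE 0.13, adjusted p = 0.00794) and Ccl2 by -1.28. The chemokine and NF-kB list had a median of -0.49 (camera adjusted p = 7.22e-10, adjusted p = 0.047 with an estimated correlation). Of 13 complement and acute phase genes, 0 rose, 4 fell and 9 did not pass (0 rose and 4 fell adjusted over the list alone). Lbp changed by -1.11 and Cp by -0.91. The complement and acute phase list had a median of -0.28 (camera adjusted p = 0.000357, adjusted p = 0.114 with an estimated correlation). C4b differed by -0.24 (adjusted p = 0.421) and Cfi by -0.15 (adjusted p = 0.822). Of 13 immediate early genes, 0 rose, 4 fell and 9 did not pass (0 rose and 8 fell adjusted over the list alone). Atf3 changed by -0.86 (SE 0.12, adjusted p = 0.00815) and Btg2 by -0.89. The immediate early list had a median of -0.74 (camera adjusted p = 4.94e-06, adjusted p = 0.138 with an estimated correlation). None of the 26 cell cycle genes was called by limma, over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05, while the list passed camera. The cell cycle list had a median of -0.29 (camera adjusted p = 1.01e-05, adjusted p = 0.139 with an estimated correlation). None of the 17 interferon response genes was called by limma over all genes, 1 rose and 2 fell when adjusted over the list alone, and 6 had an unadjusted p under 0.05. The interferon list had a median of -0.23 (camera adjusted p = 0.0196, adjusted p = 0.489 with an estimated correlation). The interferon list's call ended without CBDL_164 (adjusted p = 0.157), CBDL_170 (0.0781) or norUDCA_CBDL_179 (0.0709). Ccl2 (adjusted p up to 0.0815) and Btg2 (0.0551) lost their call without at least 1 array. Without norUDCA_CBDL_175, 14 matrix, 5 tubular injury, 4 macrophage, 1 chemokine and NF-kB and 1 immediate early genes fell.

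Of 22 proximal tubule markers, 16 rose, 0 fell and 6 did not pass (22 rose and 0 fell adjusted over the list alone). Slc22a12 changed by 1.40 (SE 0.18, adjusted p = 0.00785), Slc6a19 by 1.05 and Lrp2 by 0.98. The proximal tubule list had a median of 1.16 (camera adjusted p = 6.54e-19, adjusted p = 0.138 with an estimated correlation). Of 14 markers of the thick ascending limb and distal convoluted tubule, 3 rose, 0 fell and 11 did not pass (9 rose and 1 fell adjusted over the list alone). Klhl3, a regulator of sodium chloride transport, changed by 0.88 (SE 0.13, adjusted p = 0.00828). The thick ascending limb list had a median of 0.40 (camera adjusted p = 0.000104, adjusted p = 0.133 with an estimated correlation). Of 16 collecting duct markers, 4 rose, 0 fell and 12 did not pass (4 rose and 0 fell adjusted over the list alone). Aqp3 changed by 1.27 and Slc26a4 by 1.45. The collecting duct list had a median of 0.46 (camera adjusted p = 1.88e-06, adjusted p = 0.153 with an estimated correlation). Aqp2 differed by 0.83 (adjusted p = 0.213). Of 17 respiratory chain genes, 8 rose, 0 fell and 9 did not pass (15 rose and 0 fell adjusted over the list alone). Cyc1 changed by 0.66 and Sdhb by 0.57. The respiratory chain list had a median of 0.41 (camera adjusted p = 1.8e-12, adjusted p = 0.132 with an estimated correlation). Of 21 genes of fatty acid oxidation and PPARA targets, 7 rose, 0 fell and 14 did not pass (12 rose and 0 fell adjusted over the list alone). Acaa1b changed by 1.09 (SE 0.13, adjusted p = 0.00655) and Cyp4a14 by 1.22. The fatty acid oxidation list had a median of 0.44 (camera adjusted p = 1.07e-07, adjusted p = 0.178 with an estimated correlation). Of 16 cholesterol biosynthesis genes, 6 rose, 0 fell and 10 did not pass (12 rose and 0 fell adjusted over the list alone). Insig1, a sterol-sensing regulator, changed by 1.22 (SE 0.18, adjusted p = 0.00883), Nsdhl by 1.13 and Hmgcs1 by 0.79. The cholesterol biosynthesis list had a median of 0.68 (camera adjusted p = 7.66e-10, adjusted p = 0.139 with an estimated correlation). Of 22 genes of bile acid transport and metabolism, 3 rose, 0 fell and 19 did not pass (9 rose and 0 fell adjusted over the list alone). Slco4c1 changed by 1.28 (SE 0.20, adjusted p = 0.0091) and Abcc2 by 0.78. The bile acid list had a median of 0.31 (camera adjusted p = 0.000895, adjusted p = 0.139 with an estimated correlation). Slc10a2 differed by 0.76 (adjusted p = 0.184), Slc51a by 1.52 (adjusted p = 0.0928) and Abcc4 by -0.21 (adjusted p = 0.521). Of 11 male-biased genes, 3 rose, 0 fell and 8 did not pass (5 rose and 0 fell adjusted over the list alone). Slc22a28 changed by 2.14. The male-biased list had a median of 0.47 (camera adjusted p = 0.000326, adjusted p = 0.303 with an estimated correlation). It did not pass fry (adjusted p = 0.121). Of the genes given as examples in this paragraph, Slc26a4 (adjusted p up to 0.114), Aqp3 (0.106), Slc22a28 (0.0948), Hmgcs1 (0.0906), Lrp2 (0.0761), Abcc2 (0.0692), Nsdhl (0.0676), Sdhb (0.0611), Cyc1 (0.0595), Cyp4a14 (0.0573) and Slc6a19 (0.0529) lost their call without at least 1 array. The genes that rose were as few as 1 of the proximal tubule and 1 of fatty acid oxidation (without CBDL_164), 0 of the respiratory chain (without norUDCA_CBDL_175) and 0 of the collecting duct and of the male-biased list (without norUDCA_CBDL_172). Among the lists of cholesterol biosynthesis, bile acids and the thick ascending limb 1 gene each rose without norUDCA_CBDL_175.

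Of the 9 adipose markers Adipoq fell by 1.48 (adjusted p = 0.0148), 2 fell when adjusted over the list alone, and the list passed camera. The adipose list had a median of -0.35 (camera adjusted p = 0.00928, adjusted p = 0.468 with an estimated correlation). It moved in the same direction as the matrix, injury and macrophage lists. Its call ended without CBDL_170 (adjusted p = 0.197) or norUDCA_CBDL_172 (0.0516), and Adipoq's without CBDL_164 (0.0597) or norUDCA_CBDL_175 (0.0554). The circadian clock list missed the threshold (median 0.12, camera adjusted p = 0.0525) and passed without CBDL_165 (adjusted p = 0.0243), CBDL_170 (0.0181) or norUDCA_CBDL_172 (0.0293), and 2 of its 14 genes rose, Nr1d1 at 1.01 and Hlf at 0.97, as when adjusted over the list alone. Of 11 genes of the renin-angiotensin system and vascular tone, 2 rose and 1 fell (2 and 2 adjusted over the list alone). Ace changed by 0.85 and Edn1 by -1.47 (list median 0.01, mean -0.09, camera adjusted p = 0.943). Of 14 hypoxia and glycolysis genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone). Vegfa changed by 0.40, and Hk2 is given above. The hypoxia list had a median of 0.01 (camera adjusted p = 0.632). Of 18 NRF2 and xenobiotic genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone). Ces1f changed by 2.05. The NRF2 list had a median of 0.05 (camera adjusted p = 0.304). The sign of that median turned to -0.02 when quantile normalization was repeated. Of 12 endothelial markers, 1 rose and 0 fell (3 and 0 adjusted over the list alone). Kdr changed by 0.60. The endothelial list had a median of 0.07 (camera adjusted p = 0.192, and 0.0311 without CBDL_170). limma called 0 genes over all genes and 0 adjusted over the list alone among the stress response genes (unadjusted 1), podocyte (unadjusted 5), lymphocyte (unadjusted 0), neutrophil (unadjusted 2), urothelial (unadjusted 1) and adrenal markers (unadjusted 1). Their camera adjusted p values were 0.632, 0.709, 0.654, 0.124, 0.099 and 0.632 and their medians 0.08, 0.04, 0 to 2 decimals, -0.19, -0.47 and 0.04. The lymphocyte list passed without CBDL_165 (adjusted p = 0.0109), the neutrophil list without CBDL_170 (0.0217) and the urothelial list without CBDL_165 (0.00245) or norUDCA_CBDL_179 (0.0432). Slc4a1 differed by 1.27 (adjusted p = 0.131). Ces1f (adjusted p up to 0.15), Ace (0.114), Edn1 (0.11), Vegfa (0.105), Kdr (0.0965), Nr1d1 (0.0647) and Hlf (0.0598) lost their call without at least 1 array. Without norUDCA_CBDL_175, 0 genes rose in the circadian, renin-angiotensin, hypoxia, NRF2 and endothelial lists, where limma called them in the fit of all 9 arrays. Camera passed 17 of the 28 lists, 8 higher and 9 lower, of which that of chemokines, adhesion and NF-kB targets kept its call with an estimated correlation, and fry passed 14.

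**Figure D2:**
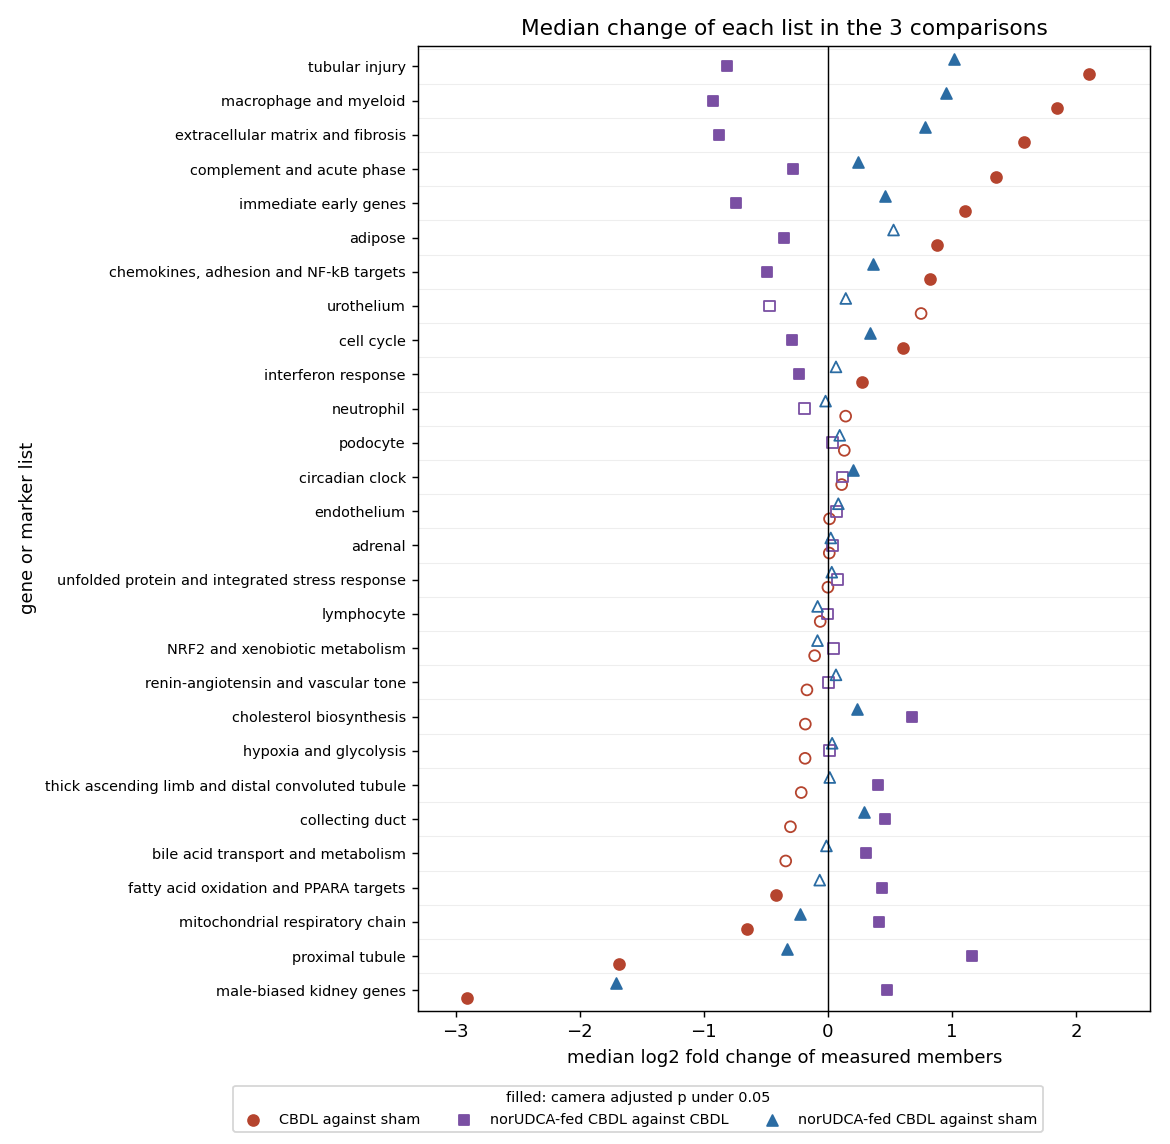
Median log2 fold change of the measured members (horizontal axis) of each of 28 gene and marker lists (vertical axis), with circles for CBDL against sham, squares for norUDCA-fed CBDL against CBDL and triangles for norUDCA-fed CBDL against sham, filled where camera gave an adjusted p under 0.05. The tubular injury list had medians of 2.10, -0.82 and 1.02 and the proximal tubule list of -1.68, 1.16 and -0.33.

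The count of 1509 fell to 361 without CBDL_164, 695 without CBDL_165, 504 without norUDCA_CBDL_172, 278 without norUDCA_CBDL_175 and 571 without norUDCA_CBDL_179, and 51 of the 89 named genes called here lost their call without at least 1 array (47 of them without norUDCA_CBDL_175), with adjusted p values up to 0.159. It was 25 with unmoderated variances, 912 with only the 6 arrays compared in the fit and 471 with every row of the value table tested, and with each array centred on its median 65.5% of 1870 called genes were higher against 53% in the values as deposited.

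The comparison of norUDCA-fed CBDL with sham addresses how far ligated kidneys of the norUDCA-fed group still differ from kidneys with a sham operation. Against sham 13 of 22 tubular injury, 15 of 27 matrix, 13 of 20 macrophage and 5 of 26 cell cycle genes rose, and 6 of 11 male-biased kidney genes fell. The male-biased list passed camera but did not pass with an estimated correlation (adjusted p = 0.105), while the other 4 lists passed both. Without norUDCA_CBDL_179 the counts that rose were 9, 7, 3 and 2 in the same order. Lcn2 was 11.12 ± 0.12 in norUDCA-fed CBDL and 7.43 ± 0.38 in sham (SD, n = 3 each), and Cyp4a14 was 10.05 ± 0.46 and 5.99 ± 0.28 (SD, n = 3 each). Of 22180 genes, 706 were called (3.2%), of which 403 rose and 303 fell, and 194 differed at least 2-fold (121 higher and 73 lower). An unadjusted p under 0.05 was reached by 3626 genes, and the arrays of the groups did not overlap for 4988 genes (22.5%, where chance gives 10%).

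The largest increases were those of Cyp4a14 at 4.06 (SE 0.22, adjusted p = 6.14e-05), Havcr1 at 4.03 (SE 0.43, adjusted p = 0.00196), Serpina3n at 3.77 (SE 0.34, adjusted p = 0.000886), Lcn2 at 3.69 (SE 0.20, adjusted p = 6.14e-05), Timp1 at 2.94, the complement gene Cfi at 2.72, Serpina10 at 2.65, Krt20 at 2.62, Gpc3 at 2.43 and Il1f6 at 2.11. The largest decreases were those of the predicted gene Gm6300 at -4.92 (SE 0.62, adjusted p = 0.0044), Pzp at -3.42, Dnase1 at -3.29 (SE 0.32, adjusted p = 0.00124), Cyp4a12a at -3.04 (SE 0.31, adjusted p = 0.00144), Slco1a1 at -3.00, the sequence AA536875 at -2.92, Hrg at -2.79, Smcp at -2.70, Akr1c14 at -2.69 and Ugt2b37 at -2.64. The norUDCA-fed means of Gm6300, AA536875, Hrg and Smcp and the sham means of Krt20 and Timp1 were under 5.2, so the size and ranking of these differences are open. Slco1a1 lost its call without sham_159 (adjusted p = 0.0574), sham_160 (0.0643), norUDCA_CBDL_172 (0.0506) or norUDCA_CBDL_179 (0.0584). Akr1c14 lost it without norUDCA_CBDL_172 (0.0511) or norUDCA_CBDL_179 (0.0526).

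Of 22 tubular injury genes, 13 rose, 0 fell and 9 did not pass (21 rose and 0 fell adjusted over the list alone). The tubular injury list had a median of 1.02 (camera adjusted p = 4.89e-31, adjusted p = 0.024 with an estimated correlation). Vcam1 changed by 1.63 (SE 0.16, adjusted p = 0.00118), Cd44 by 1.49 and Sox9 by 1.69. Of 27 matrix and fibrosis genes, 15 rose, 0 fell and 12 did not pass (25 rose and 0 fell adjusted over the list alone). Col1a1 changed by 1.57 (SE 0.17, adjusted p = 0.00245). The matrix list had a median of 0.78 (camera adjusted p = 2.13e-29, adjusted p = 0.0482 with an estimated correlation). Of 20 macrophage and myeloid markers, 13 rose, 0 fell and 7 did not pass (14 rose and 0 fell adjusted over the list alone). Mrc1 changed by 1.69 and Ctss by 1.27. The macrophage list had a median of 0.95 (camera adjusted p = 9.99e-20, adjusted p = 0.0482 with an estimated correlation). Of 20 genes of chemokines, adhesion and NF-kB targets, 5 rose, 0 fell and 15 did not pass (9 rose and 0 fell adjusted over the list alone). Cxcl1 changed by 1.20. The chemokine and NF-kB list had a median of 0.37 (camera adjusted p = 8.5e-10, adjusted p = 0.024 with an estimated correlation). Ccl2 differed by 0.31 (adjusted p = 0.6). Of 13 complement and acute phase genes, 5 rose, 0 fell and 8 did not pass (5 rose and 0 fell adjusted over the list alone). C4b changed by 1.78 (SE 0.14, adjusted p = 0.000566) and Cp by 1.62. The complement and acute phase list had a median of 0.24 (camera adjusted p = 3.81e-06, adjusted p = 0.0482 with an estimated correlation). Of 26 cell cycle genes, 5 rose, 0 fell and 21 did not pass (10 rose and 0 fell adjusted over the list alone). Mki67 changed by 1.32 (SE 0.17, adjusted p = 0.00513) and Mcm5 by 0.81. The cell cycle list had a median of 0.34 (camera adjusted p = 8.42e-13, adjusted p = 0.0482 with an estimated correlation). Ctss (adjusted p = 0.0535) and Mrc1 (0.0586) lost their call without norUDCA_CBDL_179, and Cxcl1 without norUDCA_CBDL_172 or norUDCA_CBDL_179 (up to 0.0644). Without norUDCA_CBDL_179, 0 chemokine and NF-kB genes and 3 complement and acute phase genes rose. limma called none of the 13 immediate early genes over all genes, while 7 rose when adjusted over the list alone and 7 had an unadjusted p under 0.05. The immediate early list had a median of 0.46 (camera adjusted p = 4.3e-07, adjusted p = 0.105 with an estimated correlation).

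Of 11 male-biased kidney genes, 0 rose, 6 fell and 5 did not pass (0 rose and 8 fell adjusted over the list alone). Ugt2b38 changed by -1.82 and Cyp2j13 by -1.64. The male-biased list had a median of -1.71 (camera adjusted p = 2.23e-11, adjusted p = 0.105 with an estimated correlation). Of 22 proximal tubule markers, 1 rose, 2 fell and 19 did not pass (1 rose and 3 fell adjusted over the list alone). Slc22a7 changed by -2.44, Slc17a3 by -1.15 and Slc13a1 by 0.86. The proximal tubule list had a median of -0.33 (camera adjusted p = 0.0034, adjusted p = 0.597 with an estimated correlation). That call ended without sham_160 (adjusted p = 0.0568) and with fry (adjusted p = 0.437). limma called none of the 17 respiratory chain genes over all genes, 3 fell when adjusted over the list alone and 7 had an unadjusted p under 0.05. The respiratory chain list had a median of -0.22 (camera adjusted p = 0.000405, adjusted p = 0.403 with an estimated correlation, fry adjusted p = 0.0624). Of 16 cholesterol biosynthesis genes, 2 rose, 0 fell and 14 did not pass (5 rose and 0 fell adjusted over the list alone). Insig1 changed by 1.09. The cholesterol biosynthesis list had a median of 0.23 (camera adjusted p = 4.5e-05, adjusted p = 0.372 with an estimated correlation). Its call ended without norUDCA_CBDL_175 (adjusted p = 0.0606) and with fry (adjusted p = 0.23). Of 16 collecting duct markers, 2 rose, 0 fell and 14 did not pass (3 rose and 0 fell adjusted over the list alone). Scnn1a changed by 0.57 and Atp6v0d2 by 0.65. The collecting duct list had a median of 0.29 (camera adjusted p = 0.000405, adjusted p = 0.372 with an estimated correlation, fry adjusted p = 0.269). Aqp2 differed by 0.33 (adjusted p = 0.676). Of 14 circadian clock genes, 2 rose, 0 fell and 12 did not pass (4 rose and 2 fell adjusted over the list alone). Per1 changed by 1.76 (SE 0.21, adjusted p = 0.00314) and Cry2 by 0.61. The circadian list had a median of 0.20 (camera adjusted p = 0.0285, adjusted p = 0.25 with an estimated correlation, fry adjusted p = 0.145). Its call ended without CBDL_165 (adjusted p = 0.05) or norUDCA_CBDL_175 (0.0735). Cry2 (adjusted p up to 0.167), Scnn1a (0.166), Slc17a3 (0.162), Slc22a7 (0.0937), Atp6v0d2 (0.091), Slc13a1 (0.0851) and Insig1 (0.077) lost their call without at least 1 array. None of the proximal tubule markers rose or fell without sham_160, none of the cholesterol biosynthesis genes rose without norUDCA_CBDL_179, none of the collecting duct markers rose without norUDCA_CBDL_172, and 1 circadian gene rose without norUDCA_CBDL_172.

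Of 22 genes of bile acid transport and metabolism, 4 rose and 2 fell (6 and 5 adjusted over the list alone) (median -0.01, mean -0.10, camera direction up with adjusted p = 0.478), with Cyp7b1 at -2.34, Slco1a1 at -3.00 and Abcc4 at 0.71. Abcc2 differed by 0.07 (adjusted p = 0.847), Slc10a2 by -0.45 (adjusted p = 0.492) and Slc51a by 0.73 (adjusted p = 0.479), and Abcc4 lost its call without sham_158, sham_160, CBDL_164 or any 1 of the norUDCA-fed arrays, with adjusted p values up to 0.123. Of 21 genes of fatty acid oxidation and PPARA targets, 1 rose and 0 fell (1 and 1 adjusted over the list alone), the riser being Cyp4a14 (median -0.07, mean 0.11, camera adjusted p = 0.961). Of 18 NRF2 and xenobiotic genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone). Gsta4 changed by 1.42 (SE 0.15, adjusted p = 0.00152) (median -0.08, mean -0.10, camera direction up with adjusted p = 0.782). Of 14 hypoxia and glycolysis genes, 1 rose and 0 fell (4 and 2 adjusted over the list alone). Hk2 changed by 0.71. The hypoxia list had a median of 0.03 (camera adjusted p = 0.28). Of 11 genes of the renin-angiotensin system and vascular tone, 0 rose and 1 fell (2 and 1 adjusted over the list alone). Ace changed by -1.21. The renin-angiotensin list had a median of 0.07 (camera adjusted p = 0.5). Of 14 markers of the thick ascending limb and distal convoluted tubule, 1 rose and 0 fell (2 and 1 adjusted over the list alone). The thick ascending limb list had a median of 0.01 (camera adjusted p = 0.23, with a median of -0.02 when arrays were centred). Trpv5, the member that rose, at 0.95, lost its call without sham_158, sham_159, sham_160, norUDCA_CBDL_172 or norUDCA_CBDL_179 (adjusted p up to 0.144). Of 10 adrenal markers Hsd3b1 was called higher, also over the list alone, but its means of 3.75 and 4.81 lie under 5.2, where signal above background is not shown. The adrenal list had a median of 0.02 (camera adjusted p = 0.415). Of 16 lymphocyte markers Cd79a fell, at -0.58, also over the list alone. The lymphocyte list had a median of -0.08 (camera adjusted p = 0.224). limma called 0 genes over all genes among the interferon (unadjusted 1), stress response (unadjusted 1), podocyte (unadjusted 1), endothelial (unadjusted 2), neutrophil (unadjusted 2), urothelial (unadjusted 0) and adipose lists (unadjusted 1), and adjusted over the list alone 1 podocyte marker rose. Their camera adjusted p values were 0.28, 0.152, 0.137, 0.0717, 0.23, 0.436 and 0.0694 and their medians 0.07, 0.03, 0.10, 0.08, -0.02, 0.14 and 0.53, and the neutrophil mean was 0.08. The adipose list passed without sham_158 (adjusted p = 0.00772) or norUDCA_CBDL_172 (0.00129), the urothelial list without sham_158 (0.0401), the podocyte (0.0368) and endothelial (0.0211) lists without sham_159, and the stress response list without sham_159 (0.0396) or norUDCA_CBDL_179 (0.037). Slc4a1 differed by -0.03 (adjusted p = 0.984). Hsd3b1 (adjusted p up to 0.166), Cd79a (0.13), Hk2 (0.0639) and Ace (0.0533) lost their call without at least 1 array. Without norUDCA_CBDL_179, 1 bile acid gene rose and 1 fell. Camera passed 13 of the 28 lists, 10 higher and 3 lower, 6 kept their call with an estimated correlation (tubular injury, matrix, macrophage, chemokines, complement and cell cycle), and fry passed 8.

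The count of 706 became 467 without sham_158, 420 without sham_159, 298 without sham_160, 206 without norUDCA_CBDL_172, 401 without norUDCA_CBDL_175, 156 without norUDCA_CBDL_179, 1638 with estimated array weights, 169 with unmoderated variances and 317 with every row of the value table tested. With each array centred on its median 45.2% of 923 called genes were higher against 57.1% as deposited, and the share was 70.7% without sham_159 and 69.1% without sham_159 and CBDL_165.

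Of the 4844 genes called in CBDL against sham, 1439 were called in the opposite direction in norUDCA-fed CBDL against CBDL (29.7%), 690 that rose with ligation and 749 that fell, and 1 was called in the same direction. Adjusted over those 4844 genes alone, 2830 were called in the opposite direction and 5 in the same. Col1a1 rose by 3.06 with ligation and was -1.49 in norUDCA-fed CBDL against CBDL, Slc22a12 went -2.11 and then 1.40, and Cyp51 went -2.03 and then 1.29, while for Havcr1 the second difference was 0.14 (adjusted p = 0.921) and for Cyp7b1 0.61 (adjusted p = 0.088). The second call of Cyp51 ended without any 1 of 6 arrays (adjusted p up to 0.12). Both comparisons share the CBDL arrays, so errors there push genes in opposite directions. Lists of these sizes drawn independently would overlap by 165.3 genes, and simulations with no effect and the same shared arrays gave a mean overlap of 0. The first value leaves out the shared arrays and the second the effects, so neither tells how much of 1439 the shared arrays add. Across genes the log2 fold changes of both comparisons had a correlation of -0.856 (simulated -0.499) and a covariance of -0.155 (simulated -0.013, difference -0.142), with genes not independent replicates. The covariance difference is what remains beyond the part that shared arrays add, while part of the excess in the count of 1439 may come from them, since 3 CBDL arrays cannot be split with at least 2 for each comparison.

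In the comparisons with sham, 680 of the 4844 genes were also called in norUDCA-fed CBDL in the same direction (14%), 383 higher in both and 297 lower in both, and 0 were called by limma in opposite directions. Lists drawn independently would share 41.7 higher and 34.8 lower genes, and simulations with no effect gave a mean of 0, with the same limits, so neither tells how much of 680 the shared sham arrays add. The correlation across genes was 0.819 (simulated 0.501) and the covariance 0.134 (simulated 0.0131, difference 0.121). Here too the covariance difference has the part of the shared arrays taken off only as simulated, with the same spread in all groups. Part of the excess in the count of 680 may come from the shared sham arrays. Serpina3n, Lcn2, Havcr1 and Timp1 were among the genes above sham in both groups and Dnase1, Pzp and Cyp4a12a among those below it in both.

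The difference of norUDCA-fed CBDL from CBDL was measured as a share of the ligation difference, with 1 CBDL array held out at a time. Genes and directions were taken from the other arrays. The share is a ratio of means over the called genes, not a value for each gene. By the labels feeding began before ligation, so a change that went back cannot be told from one that did not arise. The sham arrays both helped to name the genes and give the distance from sham, so that part of the measure is not free of the selection. The share averaged 53 ± 6.9% (SD, n = 3 held-out arrays), between 45.6% and 59.3%. It was 52.1 ± 5.1% (SD, n = 3) for genes that rose with ligation and 53.8 ± 9.2% (SD, n = 3) for genes that fell. For between 90.3% and 92.5% of the genes the norUDCA-fed mean lay on the sham side of the held-out array. The 3 values share the sham and norUDCA-fed arrays and are not independent.

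**Figure D3:**
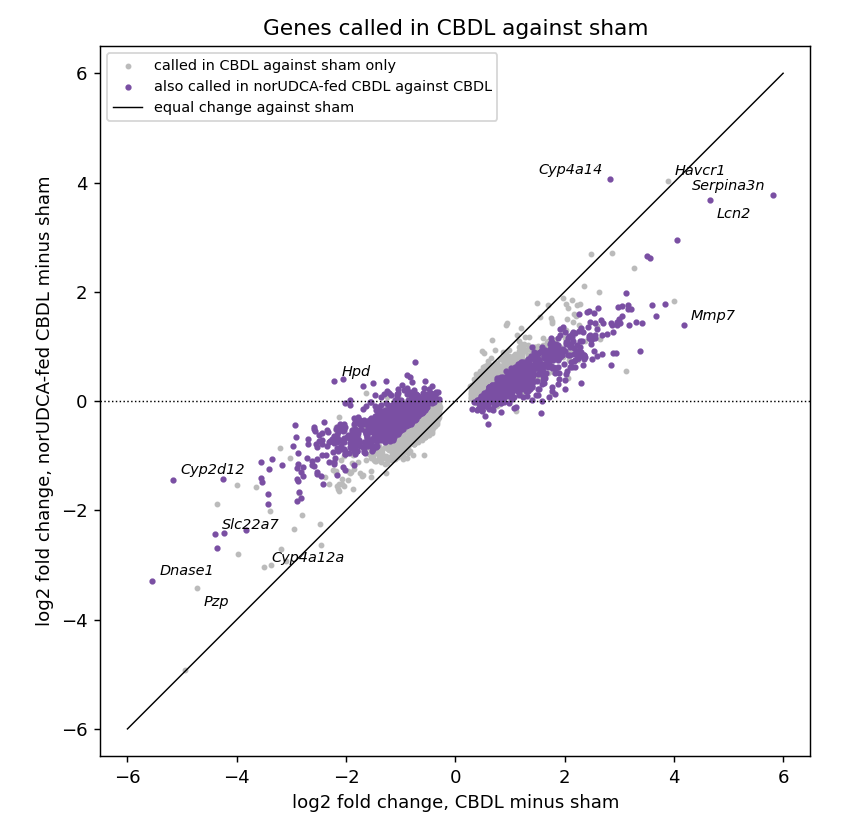
Log2 fold change of norUDCA-fed CBDL minus sham (vertical axis) against that of CBDL minus sham (horizontal axis) for each of the 4844 genes called in CBDL against sham, with 1 point per gene, genes also called in norUDCA-fed CBDL against CBDL in purple and equal change on the solid line. Havcr1 lies near that line at 3.89 and 4.03, and Mmp7 well below it at 4.18 and 1.39.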

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

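The counts of rows outside the gene tests were planned, and of the tests weighed here those on the Y-linked transcripts, the adipose correlation and the share of proximal tubule cells were chosen only after the result was seen. Rows of the value table with no gene in the annotation used, or with several, entered no comparison of genes and were tested separately with limma because a signal there is one that no gene result covers. Of the 16010 rows with no gene, 168 were called in CBDL against sham (87 higher and 81 lower), 0 in norUDCA-fed CBDL against CBDL (813 with an unadjusted p under 0.05) and 4 in norUDCA-fed CBDL against sham (all higher). Of the 1814 rows with several symbols, 273 were called in CBDL against sham (138 higher and 135 lower), 41 in norUDCA-fed CBDL against CBDL (22 and 19) and 22 in norUDCA-fed CBDL against sham (14 and 8).

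The Y-linked transcripts Kdm5d, Eif2s3y and Uty lay lower on norUDCA_CBDL_172 than on the other 8 arrays by a mean of 1.54 log2 units (34.3% of their level). Tissue of a female animal mixed in is argued against by Xist, which lay 0.73 below its highest value on the other arrays (-0.73). Weak signal on that array is argued against by 10000 random sets of 3 genes of like level, whose mean deviations ran from -0.66 to 0.84 against -1.54. A candidate explanation that stays open is loss of the Y chromosome from a share of the cells, which needs the 3 genes to fall alike, and their deviations differed by 0.2 at a residual SD of 0.17. No biological explanation among the study's groups was tested, since the pattern is on 1 array.

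Of 9 adipose markers, 3 rose in CBDL against sham, Adipoq at 2.10, Cidec at 3.13 and Retn at 2.25, and 6 did not pass, Fabp4 at 0.87 (adjusted p = 0.124) and Lep at 0.08 (adjusted p = 0.837) among them, with a list adjusted p of 0.522 under an estimated correlation. Differing amounts of adipose tissue in the samples may contribute, since the markers varied together within groups. Their mean pairwise correlation was 0.64 against a median of 0.03 and a 95th percentile of 0.21 for random lists of like signal. That correlation does not bear on the difference between groups. On CBDL_165 Adipoq (7.52), Cidec (7.62), Retn (7.98) and Cidea (6.54) lay above the sham arrays, while Fabp4 (9.92), Plin1 (5.59), Lep (4.79), Ucp1 (3.88) and Lipe (6.37) did not. None of the 9 markers is in another list used here, and 3 lay above the median of all genes in sham, where Fabp4, their brightest, was between 9.73 and 9.97. More lipid in kidney cells without adipose tissue could not be decided, as 1 of Adipoq, Retn and Lep varied within groups more than 99% of genes of like level (percentiles 95.9, 99.9 and 85.7). An effect of ligation on fat around the kidney is an untested biological explanation.

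Of 11 male-biased kidney genes, 6 stayed below sham in norUDCA-fed CBDL, with Cyp4a12a at -3.04 and Ugt2b38 at -1.82, and the list's call ended with an estimated correlation (adjusted p = 0.105). A lower share of all proximal tubule cells alone is argued against by the mean of these genes minus that of the proximal tubule markers. In norUDCA-fed CBDL it differed from sham by -1.24 (pooled SD 0.16), with arrays between -3.25 and -2.96 against -2.07 to -1.77. The markers did not move alike, since 1 of 22 rose and 2 fell in this comparison. A lower share of only some proximal tubule cells is therefore not covered by this mean and was not tested. Lower androgen action needed 3 of 4 female-biased genes to rise in CBDL against sham and was to be set aside at 1 or fewer, and 1 rose, Cyp4a14 at 2.84, with Slc7a12 at 0.25 (adjusted p = 0.727) and Slc22a19 falling, at -3.55 (adjusted p = 0.0026). This leaves it open, because Prlr was not analysed here and would make 2 if it rose. The test also cannot tell lower androgen action from a general fall of tubule transcripts, since 21 of 22 proximal tubule markers fell in that comparison. In norUDCA-fed CBDL against sham the proximal tubule list had a median of -0.33. There the values were 4.06 (adjusted p = 6.14e-05), 1.54 (adjusted p = 0.0964) and -1.11 (adjusted p = 0.414) in the same order. Probes shared between related genes of these families were not tested.

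Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05, and 1 of 10, the real split, gave as many genes in each comparison. The real counts were 4844, 1509 and 706 and the highest of the other splits 0, 1 and 0.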

How the results depend on the processing

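All alternatives were planned except leaving out sham_159 and CBDL_165 together, which was chosen after seeing the data. Going back means here that a gene called in CBDL against sham was called in the opposite direction in norUDCA-fed CBDL against CBDL. Estimated array weights gave 1638 genes in norUDCA-fed CBDL against sham and 1501 in the overlap of both comparisons with sham. Variances that are not moderated gave 25 genes in norUDCA-fed CBDL against CBDL, 169 against sham, 25 of the ligation-called genes going back and an overlap of 168, where the 6 residual degrees of freedom stand alone. With only the 6 arrays compared in the fit, 3712, 912 and 715 genes were called in the 3 comparisons and 870 went back. All rows tested gave 471 and 317 rows for norUDCA-fed CBDL against CBDL and against sham. The adjusted p with a 1.5-fold minimum gave 3160 genes in CBDL against sham, by its construction fewer. Without sham_159 and CBDL_165 the counts were 749 for norUDCA-fed CBDL against CBDL and 721 going back, and 3657 for CBDL against sham, 622 for norUDCA-fed CBDL against sham and 600 in the overlap. Leaving out 1 array at a time gave 3794 to 4604, 278 to 2043 and 156 to 822 genes in the 3 comparisons. Those going back were 264 to 1943 and the overlap 153 to 785. The 1439 going back became 351 without CBDL_164, 678 without CBDL_165 and 491, 264 and 561 without norUDCA_CBDL_172, norUDCA_CBDL_175 and norUDCA_CBDL_179. The overlap of 680 became 410 and 293 without sham_159 and sham_160. Without the same norUDCA-fed arrays it was 199, 389 and 153. Fewer arrays leave fewer degrees of freedom, but the 715 above and, without CBDL_170, 2043 and 1943 exceed the counts of all 9 arrays. The cause was not tested. Of 286 results of named genes none that was called changed direction under any alternative run; 274 kept their side of the threshold with centred arrays, 281 with repeated quantile normalization, 257 with 6 arrays in the fit and 174 with variances that are not moderated, where 110 lost their call. Of 84 list results none that passed changed direction; 49 kept their side with an estimated correlation, where 35 lost their call, 72 with fry and between 77 and 83 under the other alternatives. The interferon list in CBDL against sham also lost its call with the dimmest genes left out (adjusted p = 0.0606), with repeated quantile normalization (0.136), with fry (0.228) and with an estimated correlation (0.606). No paired analysis was possible because the numbers in the labels are not shared between groups. Signal over background limits dim genes: the dimmest 33.3% lay under a mean of 5.2, and leaving them out gave 5207, 2026 and 990 called genes in the 3 comparisons.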

Other observations

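The gene families, the genes above both groups and the arrays' own genes below were chosen only after the result was seen. Families of genes that share the start of their symbol, with at least 10 members of sufficient signal, gave further groups in CBDL against sham. Of 43 mitochondrial ribosomal protein genes (Mrpl) 26 fell and 0 rose (median -0.43, camera adjusted p = 1.34e-07, adjusted p = 0.588 with an estimated correlation), of 14 peroxisomal biogenesis genes (Pex) 9 fell (median -0.50, camera adjusted p = 1.94e-04 and 0.359), and of 10 carboxylesterase genes (Ces) 8 fell (median -1.76, camera adjusted p = 2.34e-04 and 0.478). Of 37 cytosolic ribosomal protein genes (Rpl) 13 rose (median 0.33, camera adjusted p = 6.59e-06, adjusted p = 0.466 with an estimated correlation), of 14 matrix metalloproteinase genes (Mmp) 10 rose (median 0.83, camera adjusted p = 8.73e-06 and 0.466), and of 10 annexin genes (Anxa) 8 rose and 1 fell (median 0.97, camera adjusted p = 3.34e-05 and 0.359). These directions held with arrays centred on their median (-0.53, -0.60, -1.86, 0.22, 0.73 and 0.87 in the same order) and with repeated quantile normalization. With an estimated correlation 0 of 157 families passed camera, with a lowest adjusted p of 0.359, against 47 with the preset correlation. In norUDCA-fed CBDL against CBDL 39 passed with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.431), among them Mmp with 6 of 14 lower (median -0.64) and Ces with 5 of 10 higher (median 0.77), and in norUDCA-fed CBDL against sham 26 and 0 (lowest adjusted p = 0.461).

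limma called 9 genes higher in norUDCA-fed CBDL than in both CBDL and sham and 0 lower than both. Cyp4a14 was at 1.22 (SE 0.22, adjusted p = 0.014) against CBDL and 4.06 (SE 0.22, adjusted p = 6.14e-05) against sham, Cyp27b1, the enzyme that activates vitamin D, at 1.13 (SE 0.26, adjusted p = 0.0321) and 1.56 (SE 0.26, adjusted p = 0.0131), and Cyp26b1, which degrades retinoic acid, at 0.93 and 1.51. Kynu, an enzyme of tryptophan breakdown, was at 1.07 and 1.46, Insig1 at 1.22 and 1.09, Rdh16f2 at 1.83 and 1.41, Cox6b2 at 0.68 and 0.66, Slc4a9 at 0.54 and 0.57 and the predicted gene Gm10639 at 1.55 and 1.37. Against CBDL, all of these but Insig1 lost their call without at least 1 array, with adjusted p values up to 0.145 for Cyp26b1, 0.112 for Cyp27b1 and 0.0573 for Cyp4a14. Against sham, Rdh16f2 lost its call without any 1 of 7 arrays (adjusted p up to 0.164), Cox6b2 (0.114), Slc4a9 (0.082), Gm10639 (0.0776), Insig1 (0.077), Cyp27b1 (0.0702) and Cyp26b1 (0.0516) without at least 1, and Cyp4a14 and Kynu kept it.

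Genes at least 1 log2 unit outside the range of the other 8 arrays numbered 91 on CBDL_165 and 54 on sham_159, against 2 to 12 on each of the other arrays. On CBDL_165 Vsig4 was 7.06 (at most 4.38 elsewhere), Saa3 8.09 (at most 5.46), Cxcl13 10.11 (at most 7.65) and Chil3 9.84 (at most 7.69), and Mep1b was 4.54 (at least 7.03). CBDL_164 had high values of the interferon-gamma-induced genes Cxcl9 at 8.27 (at most 6.31 elsewhere), Iigp1 at 9.66 (at most 7.75) and Gbp8 at 7.01 (at most 5.69). CBDL_170 had the urothelial markers Psca at 10.74 (at most 9.54) and Upk1b at 8.44 (at most 7.35). On norUDCA_CBDL_172 Car3, which is abundant in fat and muscle, was 5.59 against 10.25 to 12.24 elsewhere, and Depp1 was 9.43 (at most 8.24).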
